A study of Homo sapiens with 6 samples.

How the data were processed

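MiRNA levels were measured in 6 cultures of AsPC-1 cells, 3 controls and 3 overexpressing PRLR, each on 1 one-colour (Cy3) Agilent human miRNA array. Groups and replicate numbers come from the submitters' labels, which call the samples biological replicates. The labels' treatment text names alternative incubation times without tying them to samples, and the labels' extraction and labelling texts describe a blood RNA kit and cRNA amplification, which are not the usual steps for a cell line on miRNA arrays. How the RNA of these cultures was prepared and how long they were incubated is therefore not known here.

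The deposited files are scanner output, 1 file per array. Per the file headers, the spots were quantified with Agilent Feature Extraction 12.0.3.2, whereas the submitters' processing notes name version 9.1. The values used are spot intensities on a linear scale, which per the file headers are background-subtracted and not normalized between arrays. Also read were the median spot intensity with its local background, and Agilent's total signal and detection call per miRNA. All 6 arrays were hybridised on 1 slide, so slide and scan separate no samples. Control replicates 1, 2 and 3 and PRLR replicate 1 lay in slide row 1, and PRLR replicates 2 and 3 in row 2. The names in the files are those of the array's design and were used as given.

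The arrays hold 50980 spots of 5893 probes for 2549 human miRNAs, with 5 to 20 spots per probe and 1 to 4 probes per miRNA. Control spots and spots with an outlier mark were left out, and the rest were averaged per probe. A probe counted as detected on an array when at least 0.5 of its spots were well above background. Each array was divided by the 75th percentile over the 615 probes detected on all 6 arrays. That percentile was 127.8, 76.4 and 79.5 intensity units for control replicates 1, 2 and 3 and 84.1, 86.6 and 75.8 for PRLR replicates 1, 2 and 3. Values were then raised to a floor of 0.0797, the median over arrays of the lowest signal among detected probes, and log2 was taken (floor -3.65). The 675 probes detected on all 3 arrays of at least 1 group were kept, and a miRNA's value is the mean log2 over its kept probes, which left 364 miRNAs. No spot was saturated. The mean signal of the negative-control spots was -0.60 on control replicate 1 and 1.11 to 1.50 on the other 5 arrays.

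Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the tested miRNAs at 0.05, no replicate block). A miRNA detected on all arrays of one group and on none of the other was given a bound, the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest detected signal and its own. Lists were tested with camera (preset correlation 0.01) where at least 3 members were tested, with camera at an estimated correlation and fry beside it, adjusted over the 13 testable of 17 lists. fry tests whether a list's members move one way and does not compare them with other miRNAs. Of 183 names on the lists, 177 matched a name on the array, 2 of them without the arm suffix. The lists were the let-7, miR-200, miR-15/16, miR-30 and miR-29 families, the miR-17/miR-92 and miR-23/27/24 clusters, p53-responsive, NF-kB- and STAT-responsive, pancreatic ductal adenocarcinoma, acinar and islet, DLK1-DIO3, GC-rich and other-small-RNA miRNAs, and 3 lists of markers of other cell types. The number of detected miRNAs was compared with an exact permutation test.

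miRNAs were named by a rule fixed before the data were examined: the 10 risen and 10 fallen miRNAs with the largest change among those past the threshold with groups that do not overlap, or the 10 with the smallest p where fewer than 5 passed; the 10 with the highest mean signal; up to 4 members per list with the smallest p; and up to 5 per direction with the largest bound. The rule was applied to all 6 arrays and again to the comparison without control replicate 1. Members of lists were named for the comparison without control replicate 1 only, 4 each for 5 lists and 1 or 2 for the others, a narrowing chosen after the values were seen. In that comparison all called miRNAs with a bound were named. Names of miRNAs that stood out on control replicate 1 were chosen after their values were seen.

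The pipeline was tested on simulated data with the spread of the real miRNAs, 40 of 364 of them changed, in 20 simulations each. With the spread of all 6 arrays it recovered 0.2% of changes of 0.5 on the log2 scale and 9.2% of changes of 1, and 8.4% of calls were false. With the spread without control replicate 1 it recovered 85.8% and 99.2%, and 4.2% of calls were false. The simulated noise was independent between miRNAs. In the data the estimated correlation within lists ran from -0.22 to 0.76 without control replicate 1, and from 0.02 to 0.996 with all 6 arrays. These shares therefore need not hold where whole arrays shift.

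Alternatives fixed before the data were examined were the percentile over all probes, quantile normalization, normexp background correction (offset 50) with either scaling, Agilent's total gene signal, the brightest probe per miRNA, 0.5 of the floor, no filter, probes detected on all 6 arrays, an intensity trend, the replicate number as a block, other detection calls, and leaving out each array. The files used have no mean spot intensity, so normexp was run on the median spot intensity and the median local background. Its offset adds 50 intensity units to every spot, which by itself shrinks the log2 differences of dim miRNAs. Smaller differences under normexp therefore do not separate background from this shrinkage. On each array 668 to 1058 of the 5893 probes were detected, so the 75th percentile over all probes falls at the level of undetected probes. Without control replicate 1, the median standard error was 0.17 with that setting, against 0.08 with the first choice. Array weights, every alternative for the comparison without control replicate 1, and probes and scale chosen from those 5 arrays were added after the data were seen. Values set side by side come from 1 source, this fit, and no authors' normalized table was used, and no genome coordinates are given.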

Results

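Mature microRNA (miRNA) levels were measured in AsPC-1 cells, a human pancreatic adenocarcinoma line that grew out of metastatic ascites. One group of 3 cultures overexpressed the prolactin receptor (PRLR), a cytokine receptor that signals through JAK2 and STAT5, and the other group of 3 served as control. Each culture was labelled as a biological replicate and hybridised to 1 one-colour Agilent array with probes for 2549 human miRNAs. Levels are given on the log2 scale after each array was divided by the 75th percentile of its signals over the probes detected on all 6 arrays. PRLR messenger RNA is not measured by these arrays, so the overexpression itself was not checked here. The number of arrays limits the precision of every value.

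AsPC-1 cells had measurable levels of every listed member of the epithelial miR-200 family and of the let-7, miR-30 and miR-29 families. The 10 miRNAs with the highest mean signal over the 6 arrays were miR-7975, miR-7977, let-7b-5p, let-7a-5p, miR-29a-3p, miR-7641, miR-20a-5p, let-7f-5p, miR-10a-5p and miR-5100. Signals of different probes are not comparable as amounts, so this order describes brightness alone. The signal of let-7b-5p was 6.53 ± 0.50 (SD, n = 6) and that of miR-29a-3p 5.22 ± 0.55 (SD, n = 6), and without control replicate 1 they were 6.73 ± 0.13 and 5.44 ± 0.07 (SD, n = 5). The place of miR-7641 rests on control replicate 1, where it was at 7.45 against a mean of 4.03 on the other 5 arrays. Of the 31 miRNAs of the imprinted DLK1-DIO3 locus, 2 were detected on any array and 1, miR-494-3p, was tested. Of the 20 markers of other cell types, 3 were detected on every array: miR-142-3p and miR-223-3p, known from blood cells, and miR-126-3p, known from endothelium. None of the 5 fibroblast and smooth muscle markers was detected on any array.

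Control replicate 1 stood apart from the other 5 arrays. It had 563 detected miRNAs (22.1% of those on the array). Control replicates 2 and 3 had 365 each (14.3%), and PRLR replicates 1, 2 and 3 had 394, 367 and 376. Over the 364 tested miRNAs, its log2 values correlated with those of the other arrays at Pearson's r of 0.826 to 0.860. The other 5 arrays correlated with each other at 0.992 to 0.999, across miRNAs that are not independent replicates. All 26 tested members of a list of GC-rich miRNAs, whose array signal is often tied to background or RNA quality, were higher on control replicate 1 than the mean of control replicates 2 and 3, with a median difference of 2.16 on the log2 scale. The median difference of all 364 tested miRNAs was -0.69 after scaling, where that array had a divisor of 127.8 against 76.4 and 79.5. Among the settings with a detection filter, this median ran from -1.16 (Agilent's total gene signal) to -0.07 (normexp with quantile normalization). How far most miRNAs lay lower there thus depends on the scaling. With the first choice of scaling, the 11 tested members of the miR-17/miR-92 clusters (median difference -1.08) and the 9 let-7 miRNAs (-1.12) were all lower. So were all members of every other tested list except the GC-rich list and the list of miRNAs that overlap other small RNAs. The medians of the GC-rich, miR-17/miR-92 and let-7 lists kept their sign under every scaling and background setting. miR-1973 stood furthest above control replicates 2 and 3, and miR-374b-5p furthest below, with a difference of -1.57.

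**Figure D1:**
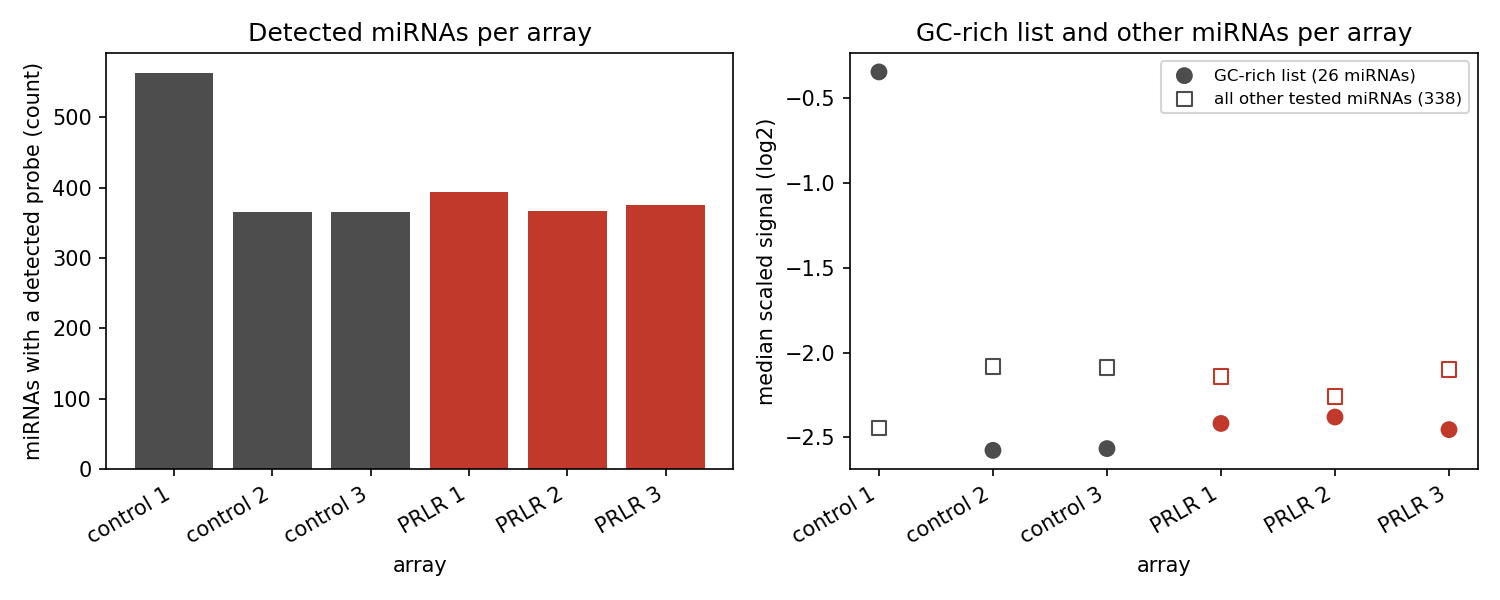
The left panel shows the number of miRNAs with at least 1 detected probe on each array, as bars from 0, and the right panel shows the median scaled signal (log2) of the 26 tested GC-rich miRNAs (filled circles) and of all other tested miRNAs (open squares) on each array, with controls in grey and PRLR in red. Control replicate 1 has 563 detected miRNAs and a GC-rich median of -0.35, while the other 5 arrays have 365 to 394 and medians between -2.58 and -2.38.

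The mean number of detected miRNAs was 431 ± 114 (SD, n = 3) in controls and 379 ± 13.7 (SD, n = 3) in PRLR cells. The difference of -52 was smaller than the spread between controls (exact permutation test, two-sided, p = 1; the smallest p that 3 against 3 arrays can give is 0.1). Without control replicate 1 the difference changed sign to 14 miRNAs (exact permutation test, two-sided, p = 0.2, with 0.1 the smallest p possible).

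The main question of the design was which miRNAs differ between PRLR-overexpressing and control cells. With all 6 arrays, 0 of the 364 tested miRNAs passed an adjusted p of 0.05 in limma's moderated test, and 3 had an unadjusted p under 0.05. limma with an intensity trend also called 0 (4 unadjusted), and limma with array weights called 62. The 10 miRNAs with the smallest p, none of which passed (adjusted p = 0.98 for each), were led by miR-1290, which overlaps U2 small nuclear RNA. Its mean log2 signal was -1.20 ± 0.25 (SD, n = 3) in controls and -0.45 ± 0.08 (SD, n = 3) in PRLR cells, a difference of 0.75 (SE 0.24, unadjusted p = 0.014). Both arms of the miR-21 hairpin, which is often high in carcinomas, followed with higher means in PRLR cells, by 0.94 (SE 0.37) for miR-21-3p and 0.54 (SE 0.26) for miR-21-5p. miR-203a-3p, a regulator of epithelial differentiation, differed by 0.78 (SE 0.32). The hypoxia-induced miR-210-3p differed by 0.76 (SE 0.38), miR-18a-5p by 0.70 (SE 0.35), miR-937-5p by 0.62 (SE 0.31) and miR-8089 by 0.54 (SE 0.26). Lower means in PRLR cells were seen for miR-30a-5p, by -0.48 (SE 0.24), and for miR-574-5p, by -0.46 (SE 0.22). No miRNA was detected on all arrays of one group and on none of the other. The median difference of all 364 miRNAs was 0.10, and it was 0.34 with the percentile over all probes and 0.28 with Agilent's total gene signal, so differences of all 6 arrays carry that uncertainty in their zero.

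The count of 0 rested on control replicate 1. Leaving out that array, 30 of the 364 miRNAs passed in limma's test, of which 25 rose and 5 fell in PRLR cells, and 86 had an unadjusted p under 0.05. No other array changed the count of 0 when left out. With array weights 62 miRNAs passed (36 higher, 26 lower), but control replicate 1 had a weight of 0.0139 there, against 1.05 to 3.82 for the other 5, so that fit nearly leaves it out and is no separate evidence for the 30. These comparisons of 2 controls with 3 PRLR arrays follow here because their median standard error was 0.08 in place of 0.30. Leaving out 1 array was planned before the data were examined, while describing this comparison in detail was chosen after control replicate 1 was seen to stand apart.

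In the comparison without control replicate 1, the largest rises were those of miR-937-5p and miR-1290, followed by miRNAs mostly on the GC-rich list. With the first choice of settings no rise with a measured size reached 2-fold. Over the other settings the highest log2 difference of miR-1290 was 1.007. It was 1.907 for miR-937-5p and 2.28 for miR-6800-5p, neither of which was well above background on either control array. Of the 25 risen miRNAs, 10 belong to the GC-rich list. miR-1290 rose 1.85-fold, from -1.34 ± 0.07 (SD, n = 2) to -0.45 ± 0.08 (SD, n = 3), with a log2 difference of 0.89 (SE 0.08, adjusted p = 2.7e-04). miR-1246, which also overlaps U2 small nuclear RNA, rose 1.34-fold (log2 difference 0.43, SE 0.09, adjusted p = 0.015). miR-3960 rose 1.66-fold (0.73, SE 0.07, adjusted p = 4.4e-04), and miR-4281, miR-4430, miR-4530, miR-6090, miR-6089 and miR-6821-5p rose by 0.73, 0.73, 0.73, 0.71, 0.64 and 0.54, and of these miR-4430 and miR-6821-5p are not on the GC-rich list. With normexp background correction the calls of miR-4281, miR-4430, miR-6821-5p, miR-3665 and miR-937-5p were lost, at differences of 0.08, 0.11, 0.03, 0.05 and 0.11. The offset of 50 shrinks differences of dim miRNAs by itself, so these losses cannot be laid to background alone. miR-3665 rose by 0.69 and was detected on 1 of the 2 control arrays. 4 of the risen miRNAs were not well above background on either control array, so their rise has only a lower bound, and miR-4466 (adjusted p = 0.054 without control replicate 2), miR-6126 (0.085 without control replicate 2, 0.050, just over the threshold, without control replicate 3) and miR-6800-5p (0.19 without either) did not pass with 1 control, nor did miR-1246 without control replicate 3 (0.20). It was at least 1.87-fold for miR-937-5p (adjusted p = 2.7e-04), at least 1.36-fold for miR-4466, at least 1.33-fold for miR-6126 and at least 1.29-fold for miR-6800-5p. The calls of the last 3 were lost under normexp as well, at differences of 0.00, -0.02 and 0.02. Under normexp with quantile normalization their adjusted p was 0.080, 0.11 and 0.12. miR-4466 also did not pass with Agilent's total gene signal (adjusted p = 0.20), nor miR-6126 with the percentile over all probes (0.051). For miR-6800-5p it was 0.20 under quantile normalization and 0.052 with probes and scale from the 5 arrays.

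Among miRNAs outside those groups, both arms of the miR-21 hairpin rose, miR-21-5p 1.27-fold (log2 difference 0.34, SE 0.07, adjusted p = 0.011) and miR-21-3p 1.44-fold (0.52, SE 0.11, adjusted p = 0.016). miR-203a-3p rose 1.35-fold (0.44, SE 0.07, adjusted p = 4.7e-03) and miR-18a-5p 1.24-fold (0.31, SE 0.07, adjusted p = 0.032). The 5 that fell were miR-30a-5p, by 0.61 on the log2 scale (SE 0.08, adjusted p = 1.0e-03), both arms of the miR-574 hairpin, miR-574-3p by -0.57 (SE 0.07) and miR-574-5p by -0.49 (SE 0.08), miR-3653-3p by -0.40 (SE 0.09) and miR-181a-5p by -0.32 (SE 0.07). The differences stayed close to these values when a further control was left out, but without control replicate 2 or 3 the adjusted p was 0.15 and 0.15 for miR-21-5p, 0.15 and 0.072 for miR-21-3p, 0.085 and 0.050 (just over the threshold) for miR-203a-3p, 0.37 and 0.17 for miR-18a-5p, 0.18 and 0.19 for miR-3653-3p and 0.21 and 0.18 for miR-181a-5p. Without PRLR replicate 1 it was 0.10 for miR-21-3p, 0.18 for miR-18a-5p, 0.10 for miR-3653-3p and 0.055 for miR-181a-5p, and without control replicate 2 it was 0.065 for miR-574-5p.

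Other settings also ended calls of this group. With the percentile over all probes the adjusted p was 0.088 for miR-574-3p (difference -0.45), 0.30 for miR-574-5p (-0.37), 0.081 for miR-21-5p (0.46) and 0.12 for miR-18a-5p (0.43). For miR-3653-3p it was 0.69 (-0.28) and for miR-181a-5p 0.997 (-0.20), which left miR-30a-5p as the 1 fallen miRNA. The median standard error was 0.17 there, against 0.08 with the first choice. With Agilent's total gene signal the adjusted p was 0.054 for both miR-21-5p (difference 0.33) and miR-21-3p (0.56) and 0.13 for miR-18a-5p (0.33). It was 0.40 for miR-3653-3p (-0.42), 0.10 for miR-181a-5p (-0.29) and 0.062 for miR-1246 (0.44). With normexp miR-21-3p was at 0.09 (adjusted p = 0.21), miR-18a-5p at 0.10 (0.21) and miR-3653-3p at -0.13 (0.085). miR-18a-5p also did not pass under quantile normalization (0.055). With a replicate block the adjusted p was 0.12 for miR-21-5p, 0.32 for miR-18a-5p, 0.14 for miR-181a-5p, 0.058 for miR-3653-3p and 0.059 for miR-6126. PRLR replicate 1 has no partner in that block and adds nothing to those differences.

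The median difference of all 364 miRNAs was -0.09, and dividing by the 75th percentile of all probes moved it to 0.03. Each of the 20 called miRNAs with more than 1 kept probe had all those probes on one side. That is partly built in, since the calls were made on the mean of those probes. The other 10 calls rest on 1 kept probe, among them miR-937-5p, miR-1290, miR-21-3p and miR-30a-5p. With no filter, which takes in probes that were not kept, the differences of these were 0.462, 0.445, 0.378 and -0.306. For miR-937-5p, miR-1290 and miR-30a-5p, that is the kept probe's difference averaged with a probe that showed none, as a probe at the floor would. The added probe thus gives no support to these 3 calls. Of the 30, 17 had the same sign with all 6 arrays. The rest, such as miR-4430 (-0.34) and miR-6089 (-0.05), had the opposite sign there, because control replicate 1 lay above the PRLR arrays.

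**Figure D2:**
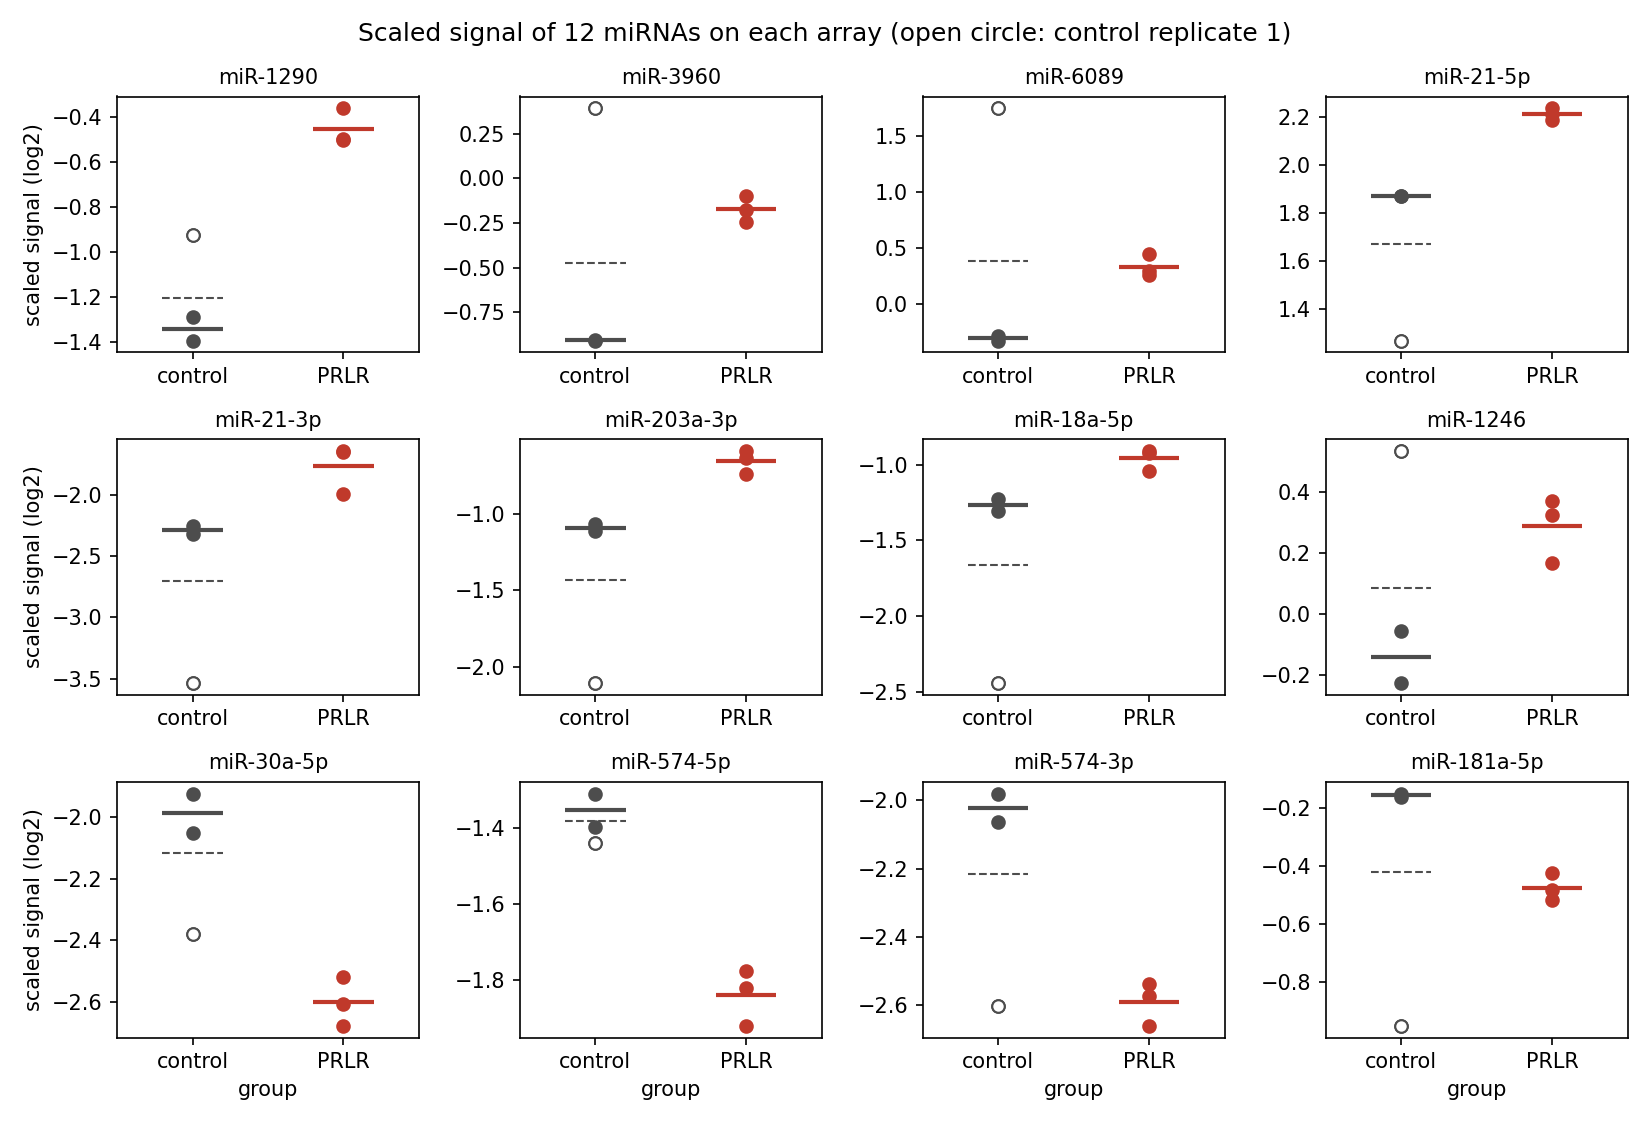
Each panel shows the scaled signal (log2) of 1 miRNA on the 3 control arrays (grey; the open circle is control replicate 1) and the 3 PRLR arrays (red), with the mean of control replicates 2 and 3 and of PRLR as solid lines and the mean of all 3 controls as a dashed line. miR-1290 is higher on all 3 PRLR arrays than on all 3 control arrays, whereas for miR-6089 control replicate 1 lies above the PRLR arrays and control replicates 2 and 3 below them.

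**Figure D3:**
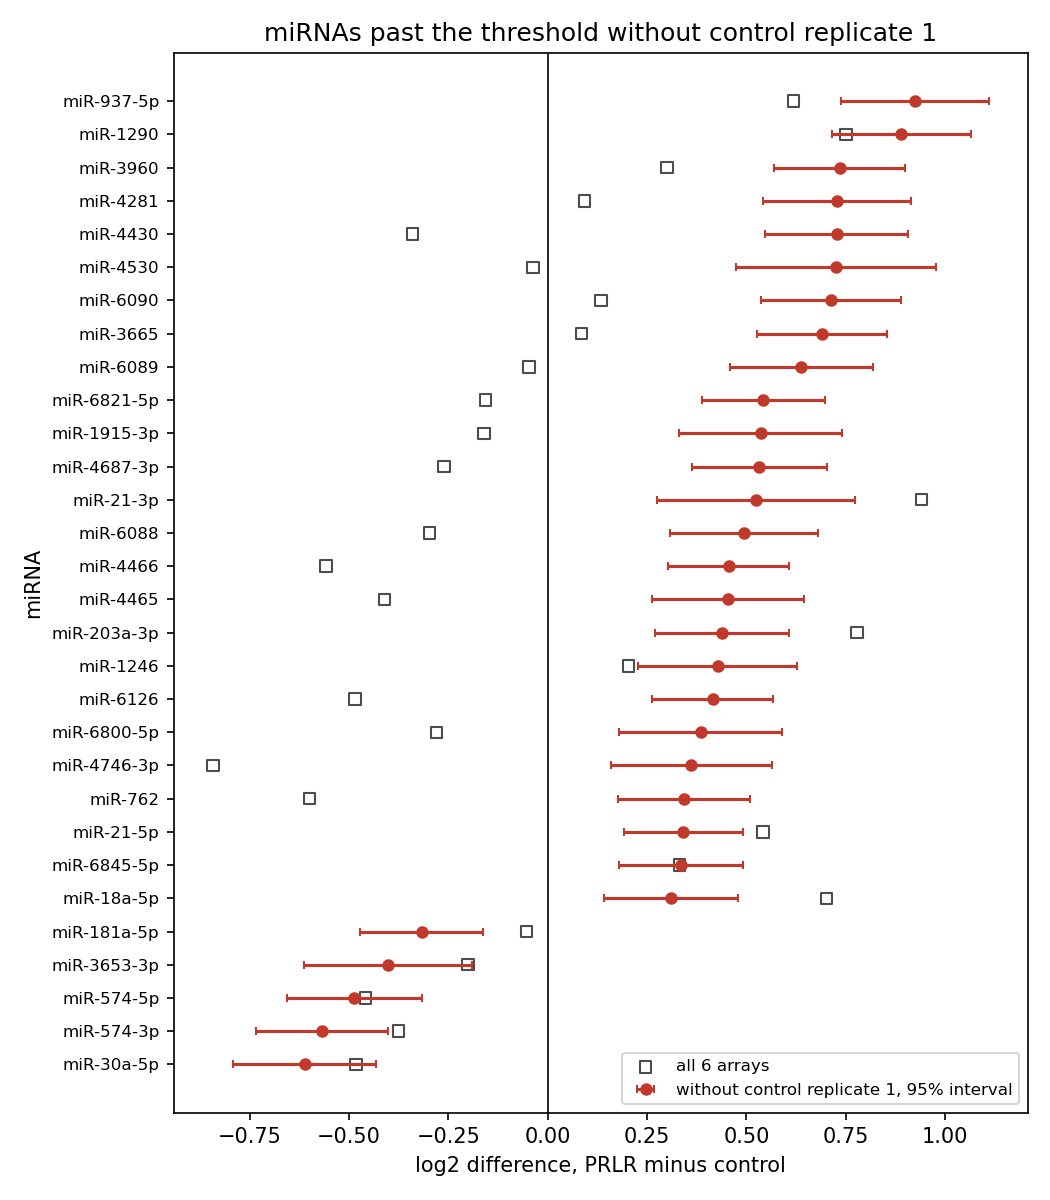
The log2 difference, PRLR minus control, is shown for the 30 miRNAs that passed without control replicate 1, as points with 95% confidence intervals, beside the difference with all 6 arrays as open squares. The 25 risen miRNAs lie between 0.31 and 0.92, and 13 of the 30 change sign when control replicate 1 is included, all of them among the risen.

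The 30 calls depended on single arrays. Without control replicate 2 as well there were 15 calls, without control replicate 3 there were 17, without PRLR replicate 2 there were 51, and without PRLR replicate 3 there were 117 (33 higher, 84 lower). With normexp background correction 31 passed, split into 15 risen and 16 fallen, and 12 of the 30 were among them. Signal of a labelling spike-in also differed between arrays. Its mean was 1144 and 1117 intensity units on control replicates 2 and 3, and 1072, 832 and 1538 on PRLR replicates 1, 2 and 3. Whether labelling bears on the calls was not tested.

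The miRNA lists, fixed before the data were examined, were tested for a common shift. With all 6 arrays, camera called 3 of 13 lists. The miR-17/miR-92 cluster and its paralogues, driven by MYC and E2F in proliferating cells, was higher in PRLR cells in all 11 members (median 0.51, adjusted p = 3.5e-05). The miRNAs commonly raised in pancreatic ductal adenocarcinoma were higher in 13 of 13 members (median 0.33, adjusted p = 1.9e-03), and the GC-rich miRNAs were lower in 22 of 26 (median -0.41, adjusted p = 1.2e-06). None of the 3 held with an estimated correlation (adjusted p = 0.65 for each) or in fry (lowest adjusted p = 0.62), and no member passed singly. Among the 10 splits of the 6 arrays into 3 and 3, 5 called at least as many lists, the labelled one included. Control replicate 1 was low in the first 2 lists and high in the third. Leaving it out turned the second to a median of -0.05 and the third to 0.20, and lowered the first to 0.14, while without control replicate 2 the medians were 0.70, 0.51 and -0.62 and without control replicate 3 -0.65 for the third. With no filter, camera's adjusted p was 0.065 for the first and 0.41 for the second. For the miR-30 family the median was 0.11 and the mean 0.01, while the test ranked it below other miRNAs (adjusted p = 0.56).

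Without control replicate 1, camera called 2 lists. The miR-17/miR-92 list was again higher, in 9 of 11 members, with a median of 0.14 (0.26 with the percentile over all probes, 0.07 under normexp with quantile normalization; adjusted p = 2.1e-03; adjusted p = 0.53 with an estimated correlation). miR-18a-5p rose, and miR-17-5p (0.23, adjusted p = 0.078), miR-20b-5p (0.20) and miR-18b-5p (0.19) did not pass, with 2 members past the threshold when adjusted over the list alone. In fry the adjusted p was 0.048, in a range over all settings from 0.036 to 0.86 (0.86 with the percentile over all probes, 0.12 with normexp), and camera's adjusted p was 0.078 without PRLR replicate 3 and 0.081 with the percentile taken over all probes, in a range over all settings from 1.1e-32 (no filter) to 0.081. The GC-rich list turned from lower to higher, in 19 of 26 members, with a median of 0.20 (adjusted p = 8.9e-11; adjusted p = 0.28 with an estimated correlation). In it 10 members rose, and 13 passed when adjusted over the list alone. In fry its adjusted p was 0.010, in a range over all settings from 6.0e-03 to 0.86 (0.86 with the percentile over all probes, 0.076 with quantile normalization, 0.44 with normexp). With normexp background correction its median was -0.01, although camera still ranked it above other miRNAs (adjusted p = 1.7e-05, the highest over all settings). The lowest was 1.4e-48, with no filter. In that setting the median standard error over 2549 miRNAs was 0, so many of the miRNAs a list is compared with do not vary. camera's small p-values with no filter, for this and every other list, are therefore no added evidence.

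The miR-30 family was lower in 5 of 5 members without control replicate 1, with a median of -0.19. miR-30a-5p fell, while miR-30c-5p (-0.23, adjusted p = 0.097), miR-30e-5p (-0.19) and miR-30b-5p (-0.06) did not pass, and 2 members passed when adjusted over the list alone. fry called this shift (adjusted p = 0.010) and camera did not (adjusted p = 0.16; 0.53 with an estimated correlation). With the percentile over all probes 2 of the 5 members were above 0 and fry's adjusted p was 0.86, in a range over all settings from 6.0e-03 to 0.86. camera's range was 3.1e-03 (no filter; adjusted p = 0.17 with an estimated correlation there) to 0.48.

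Of the 13 tested miRNAs commonly raised in pancreatic ductal adenocarcinoma, miR-203a-3p and miR-21-5p rose without control replicate 1, and none fell. miR-210-3p differed by 0.33 (adjusted p = 0.10) and miR-31-5p by -0.17 (adjusted p = 0.16). The list's median was -0.05 (0.07 with the percentile over all probes) and its mean 0.04, and camera ranked it higher (adjusted p = 0.48, fry 0.37). camera called it higher under normexp (adjusted p = 5.9e-03, median -0.01; adjusted p = 0.39 with an estimated correlation) and with no filter (adjusted p = 6.2e-08, median 0.00; adjusted p = 0.059 with an estimated correlation). Of 8 NF-kB- and STAT-responsive miRNAs, miR-21-5p rose and miR-181a-5p fell, and miR-125b-5p (-0.25, adjusted p = 0.067) and miR-181b-5p (-0.15) did not pass. This list showed no common shift (median -0.08, or 0.04 with the percentile over all probes, camera adjusted p = 0.93), and 3 members passed when adjusted over the list alone. Of 9 annotated miRNAs that overlap other small RNAs, miR-1290 and miR-1246 rose and the other 7 were lower, with a list median of -0.21 (camera adjusted p = 0.92). With the percentile over all probes the median was -0.09 and camera's direction was up (adjusted p = 0.94). All 9 passed when adjusted over the list alone.

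With the settings fixed as first choice, the remaining lists had no call in camera or fry and no member past the threshold without control replicate 1. Dividing by the percentile over all probes, which falls at the level of undetected probes, turned most of their medians. The let-7 family, broad repressors of growth genes, had a median of -0.05 (0.06 with that percentile, camera adjusted p = 0.92), with let-7b-5p at -0.21 and let-7c-5p at -0.14. The miR-200 family, which maintains epithelial identity by repressing ZEB1 and ZEB2, had a median of -0.05 (0.07 with that percentile, adjusted p = 0.92), with miR-200a-3p at -0.12 and miR-141-3p at -0.09. The p53-responsive miRNAs had a median of -0.11 (0.00 with that percentile), with miR-194-5p at -0.23 and miR-192-5p at -0.15. The acinar and islet miRNAs had a median of -0.02 (0.09 with that percentile; fry adjusted p = 0.19), with miR-148a-3p at -0.14. fry called that list of 3 lower with the brightest probe (adjusted p = 0.019), with probes detected on all 6 arrays (0.034) and with probes and scale from the 5 arrays (0.025). The miR-29 family, repressors of collagen genes, had a median of -0.07 (0.04 with that percentile), with miR-29a-3p at -0.10. For the miR-15/16 family, cell cycle repressors, the median was 0.01, the mean -0.03 and camera's direction up, with miR-195-5p at -0.23 and miR-15b-5p at 0.08. camera called this family higher with no filter alone (adjusted p = 3.5e-03; adjusted p = 0.34 with an estimated correlation). For the miR-23/27/24 clusters the median was -0.05 (0.07 with that percentile), the mean 0.01 and camera's direction up, with miR-24-3p at 0.19 and miR-23b-3p at -0.16.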

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

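Of the tests here, those of background before subtraction, of the GC-rich signal on control replicate 1, of the same shift at a smaller size in PRLR cells and of the slide row were chosen only after the result was seen, and those of background after subtraction and of RNA from other cells before.

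Detection on 1 array alone stood out. 185 miRNAs (359 probes) were detected on control replicate 1 and on no other array, while 338 were detected on every array. The brightest of the 185 were miR-513a-5p, miR-3648 and miR-4669, and 8 belong to the GC-rich list.

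A generally higher background on that array is argued against by the negative-control spots before subtraction, whose mean was 22.2 intensity units there and 24.5 to 25.7 on the other 5 arrays, a difference of -3.43 from the highest. After subtraction that difference was -2.1, which decides nothing, since subtraction sets such spots near 0. Negative-control spots cannot show background tied to GC-rich probes, which was not tested. RNA from blood, stromal, endothelial, muscle, nerve or liver cells is argued against as well, as 3 of 20 fixed markers were detected there, a difference of 0 from the highest of the other 5 arrays. Signal of GC-rich probes, as from RNA quality, is a candidate explanation that stays open. The GC-rich list stood 2.883 above all other tested miRNAs on the log2 scale, against an upper limit of 0.26 for the middle 95% of 10000 random lists. RNA quality was not measured in these files, and another culture or a mix-up of that sample was not tested.

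The GC-rich list also differed between PRLR cells and control replicates 2 and 3. Without control replicate 1, the GC-rich list lay 0.29 above all other tested miRNAs in PRLR cells, against an upper limit of 0.07 for the middle 95% of 10000 random lists, and 10 of the 25 risen miRNAs belong to it. Random lists leave out correlation between members, and camera's adjusted p was 0.28 with an estimated correlation. Under normexp, whose offset shrinks differences of dim miRNAs, the list's median was -0.011 and lay 0.06 above the median of all tested miRNAs. 17 of the 25 also stood over 1 higher (log2) on control replicate 1 than on control replicates 2 and 3, against 60 of all 364 tested, though both differences use the same 2 controls. The slide row stays open, because 1 PRLR array alone lay in the row of the controls: PRLR replicate 1 had a list shift of 0.265, with 0.38 and 0.19 in PRLR replicates 2 and 3 and 0.03 between control replicates 2 and 3. Position along the row was not tested. The shift of control replicate 1 at a smaller size cannot be told apart from a PRLR effect on these miRNAs. The 39 miRNAs outside the list that stood over 1 higher on control replicate 1 lay 0.153 above the rest in PRLR cells, and the bootstrap interval of 0.133 to 0.211 includes the 0.146 that was asked for. Chosen against one of control replicates 2 and 3 and measured against the other, their shift was 0.117 and 0.198, beside list shifts of 0.258 and 0.317, so that 0.5 of the list's shift was missed in the first and reached in the second. A PRLR effect on these miRNAs remains among the open explanations, untested.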

How the results depend on the processing

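The array weights and every setting applied to the comparison without control replicate 1 were chosen after the result was seen. With all 6 arrays the count of 0 called miRNAs was the same in 10 settings that kept every array, with 2 to 18 miRNAs at an unadjusted p under 0.05. It was 1 under normexp with quantile normalization and 62 under array weights. The counts of called miRNAs were 0 to 30 when single arrays were left out, the 30 without control replicate 1. The 3 called lists became 0 with an estimated correlation, 0 in fry, 5 under quantile normalization, 7 under normexp and 5 under normexp with quantile normalization, and 2 to 4 when single arrays were left out. The median of the pancreatic ductal adenocarcinoma list turned from 0.33 to -0.047 without control replicate 1 and was 0.505 without control replicate 2, and that of the GC-rich list turned from -0.41 to 0.196 without control replicate 1 and was -0.652 without control replicate 3. The difference in detected miRNAs was -85 to 14 when single arrays were left out, with 14 only without control replicate 1. The cause of these changes was not tested beyond the array left out.

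Without control replicate 1, the 30 calls became 56 with an intensity trend and 0 with no filter (76 at an unadjusted p under 0.05), where the median standard error over 2549 miRNAs was 0. They were 22 to 39 in the other settings that kept the 5 arrays, and 15 to 117 when a further array was left out. Leaving out 1 of the 2 controls leaves a lone array that is assumed to vary like the PRLR arrays. The split into risen and fallen was 25 and 5, and became 21 and 1 with the percentile over all probes, 20 and 10 under quantile normalization, 15 and 16 under normexp and 24 and 15 under normexp with quantile normalization. The 2 called lists became 0 with an estimated correlation, 1 with the percentile over all probes, 5 with no filter and 1 to 2 when a further array was left out. The GC-rich median turned to -0.011 under normexp, as did miR-6126, which lies near the floor, to -0.017. The offset used there shrinks differences of dim miRNAs, and the median of all tested miRNAs was -0.07. With the percentile over all probes, miR-200a-3p turned to 0.001, miR-141-3p to 0.030, miR-30b-5p to 0.062 and miR-29a-3p to 0.022. The cause was not tested. Of 777 other values of 46 named miRNAs, 648 kept their direction and side of the threshold, 83 lost the threshold and 41 gained it. miR-1290, miR-3960, miR-4530, miR-6090, miR-6089 and miR-30a-5p passed in every setting except no filter.

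Whether the replicate numbers pair the samples cannot be judged. Deviations from the group means correlated at -0.02, -0.39 and 0.38 for numbers 1, 2 and 3. In the controls these deviations mostly carry the distance of control replicate 1. Its differences from control replicates 2 and 3 had an SD of 1.28 and 1.25, against 0.09 between those 2. With a replicate block, 0 miRNAs passed with all 6 arrays (18 unadjusted) and 22 without control replicate 1, all among the 30, and camera called 3 and 2 lists. Without control replicate 1, PRLR replicate 1 has no partner in that block and adds nothing to the group difference. That fit thus gives the differences found without PRLR replicate 1 (GC-rich median 0.208 in both) and is no separate check. The slide as a block was not run, because 1 slide holds all arrays, and the intensity trend has no list test. The 10 splits of the 6 arrays into 3 and 3 are too few to judge chance: the labelled one gave 0 miRNAs and 3 lists, and the highest of the others gave 0 and 4; 10 splits gave as many miRNAs and 5 as many lists. Signal over background limits the dim miRNAs, since 675 of 5893 probes were kept.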

Other observations

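The test of paired hairpin arms was set before its result was seen, and after both arms of miR-21 and miR-574 had been seen to move. A few miRNAs not yet described also rose without control replicate 1: miR-1915-3p, miR-4687-3p, miR-6088, miR-4465, miR-4746-3p, miR-762 and miR-6845-5p, with log2 differences between 0.34 and 0.54. They are named here after their values were seen, and they did not pass under normexp. Several annotated miRNAs that overlap other small RNAs moved apart: miR-1290 and miR-1246 rose, and miR-5100, miR-7977 and miR-7975 had differences of -0.26, -0.23 and -0.23, none of which passed over all miRNAs. On control replicate 1, miR-7641 was at 7.45 against 4.02 for control replicates 2 and 3, and miR-494-3p at 5.44 against 2.06.

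Both arms of the miR-21 hairpin rose and both arms of the miR-574 hairpin fell without control replicate 1. If a shared precursor transcript moved the arms together, the same could hold over the other hairpins with both arms measured. Over 27 hairpins, leaving out miR-21 and miR-574, the Spearman rho of the log2 differences of the arms was 0.278 (permutation test, two-sided, 10000 permutations, p = 0.16), which does not settle it. With those 2 hairpins rho was 0.41 over 29 (p = 0.032), which rests on the hairpins that prompted the test. Between control replicates 2 and 3 rho was 0.06 (p = 0.77) over the 27. These correlations are across hairpins, which are not independent replicates.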
